A study of Mus musculus with 3 samples.

How the data were processed

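Peripheral blood mononuclear cells of C57BL/6 mice had been separated over lymphocyte separation medium and loaded on the 10x Chromium with the Single Cell 3' v3 kit, per the labels' protocols, which give no number of mice per library. The deposited values were UMI counts per gene and barcode for all barcodes, made with Cell Ranger 4, per the file headers. The submitters' processing notes also list the genome build mm10 and Seurat 3.1.0, without saying which filters were set. No cell annotation of the authors was used. Each of the 3 libraries was its own group (young with PBS, aged with PBS, aged with AA), taken from the labels. Gene positions came from the GENCODE M21 annotation of GRCm38.

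From the deposited counts, barcodes were called as cells in Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1. A barcode passed with at least a fraction 1/10 of the UMIs at the 99th percentile of the top 5000 barcodes, or, from 500 UMIs, when its profile differed from free RNA at a false discovery rate of 0.01 by 10000 simulated draws. Free RNA was the sum of the barcodes ranked 45001 to 90000 by UMIs. This called 10841 young, 16236 aged and 14381 aged+AA barcodes. Cells then needed at least 500 UMIs, at least 250 genes and at most 10% mitochondrial UMIs, which left out 1212, 5837 and 2279 barcodes by genes and 489, 216 and 542 by mitochondrial share. Scrublet in scanpy 1.11.5, run per library, removed 457, 418 and 471 predicted doublets (5.00%, 4.11% and 4.07%).

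Counts were log-normalised to 10000 per cell, and 2000 variable genes without immunoglobulin, T-cell receptor, haemoglobin, mitochondrial, Xist, Tsix and Y-linked genes gave 30 components, 15 neighbours and Leiden clusters at resolution 1.0 (igraph 0.11.9), for the 3 libraries together and without batch correction. Clusters led by T or NK markers were clustered again with the same settings. Markers were fixed before the data were examined. The naming rules were set afterwards: a marker counted for a cluster from 20 CPM and 25% of its level in the highest cluster, a class needed 3 or more detected markers, and a cluster with Cd8a and Cd8b1 but not Cd4 was CD8 T-like, the reverse CD4 T-like. Clusters with erythroid genes and at least 60% of the T or B markers were called mixed.

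Counts were summed per library and class and scaled to CPM. Classes with at least 50 cells in both libraries were compared, which left 4 of the 5 planned classes. A list's value was the median log2 ratio of its genes with at least 20 counts over the 3 libraries, 0.5 being added to each count, and its percentile came from 10000 random lists of the same size matched in 20 bins of expression. List intervals came from 2000 Poisson redraws. There were 20 gene lists, fixed before the data were examined. Free RNA per class was estimated from the haemoglobin UMIs of the median cell over those of free RNA. Shares of cells with a UMI were taken after thinning each cell to 1000 UMIs. A count of 0 was set against a floor of 3 counts.

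Genes were named by a rule fixed before the data were examined: in each class and comparison, genes with at least 50 counts in the higher library were ranked by the 95% bound of their ratio nearest to 1. The top 4 each way were taken in CD8 T-like, 3 in CD4 T-like and B-like and 2 in NK-like cells, without immunoglobulin, T-cell receptor, haemoglobin, mitochondrial, ribosomal, Xist, Tsix, Y-linked and clone-named genes. Myh9, Cd8a, Cd8b1, Cd4 and list members with the most counts or largest ratios were added.

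The ratio step was tested on counts simulated from the CD8 T-like sums, with 200 changed genes per comparison. For aged over young, over 7866 genes, true folds of 2, 4, 0.5 and 0.25 gave median ratios of 1.99, 4.01, 0.508 and 0.247, and the 95% interval held the truth for 90.0%, 96.0%, 98.0% and 96.0% of genes. For aged+AA over aged, over 8515 genes, they gave 2.02, 3.93, 0.516 and 0.252, and the interval held the truth for 98.0%, 98.0%, 96.0% and 96.0%.

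Alternatives covered cell calling, the mitochondrial limit, doublet removal, clustering resolution, clustering each library on its own, a per-cell UMI gate in place of clusters, other scalings, free RNA removal and other denominators. Figures were drawn with matplotlib 3.10.9. Mouse-level differences, other tissues and the gut microbiota were not analysed here.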

Results

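Single-cell RNA profiles of peripheral blood mononuclear cells were compared between 3 libraries of C57BL/6 mice, with 1 library per group. The groups were young mice given PBS, aged mice given PBS, and aged mice given AA for 1 month, AA being ascorbic acid by the series title, which also names CD8+ T cells and the Myh9 protein. The young, aged and aged+AA libraries held 64496639, 94944551 and 80424480 unique molecular identifiers (UMIs), each UMI marking 1 captured RNA molecule. After filtering, 8683 young, 9765 aged and 11089 aged+AA cells remained, with median depths of 4441, 3610 and 4055 UMIs per cell. With 1 library per group, differences between libraries have no replicate check and no test was made. The 95% intervals given with shares (exact binomial), CPM (counts scaled to a common total, exact Poisson) and ratios (exact conditional binomial) cover counting error only.

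The comparison of the aged with the young library asked how the blood differed with age. T-like cells made up 62.1% of the young cells and 22.0% of the aged cells, while monocyte-like, neutrophil-like and B-like cells held larger shares of the aged library. CD8 T-like cells, the class with RNA of the CD8 co-receptor genes Cd8a and Cd8b1, fell from 2000 of 8683 young cells (23.03%, 22.2 to 23.9%) to 978 of 9765 aged cells (10.0%, 9.43 to 10.6%), a ratio of 0.435 (0.402 to 0.470). CD4 T-like cells held 38.1% of young and 10.9% of aged cells, a ratio of 0.287 (0.268 to 0.308). B-like cells held 27.8% of young and 38.7% of aged cells, a ratio of 1.40 (1.33 to 1.47). It was 2.44 (2.25 to 2.66) when cells had at most 5% mitochondrial UMIs, a limit that kept 4032 of the young but 9164 of the aged cells. NK-like cells held 4.24% of young and 3.26% of aged cells.

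Myeloid classes held larger shares of the aged than of the young library. Classical monocyte-like cells numbered 2 in the young and 835 in the aged library (8.55%), a ratio of 371 with an interval of 102 to 3071. Non-classical monocyte-like cells held 0.737% and 5.75%, and neutrophil-like cells 0.207% and 8.75%. No basophil-like cell was found among the 8683 young cells, against 153 cells (1.57%) in the aged library. The exact binomial interval of the young share reached 0.0425%, and the floor of 3 counts stood at 0.0346%. Plasma-like cells, a class led by genes of antibody-secreting cells, held 0.0806% and 1.01%. Over the 3 libraries 39.0% of this cluster's cells also had a UMI of the T-cell gene Cd3e, so the class may hold other cells too. Among T-, B- and NK-like cells alone, CD8 T-like cells held 24.5% in the young and 15.6% in the aged library (ratio 0.639, 0.591 to 0.690), CD4 T-like cells 40.5% and 17.1%, and B-like cells 29.5% and 60.5%. NK-like cells held 4.51% and 5.09% on this denominator (ratio 1.13, 0.969 to 1.32), so their lower share of all aged cells depended on the denominator. Among T-like cells the CD8 T-like share was 37.1% in the young and 45.5% in the aged library. This difference was lost at resolution 0.5 (ratio 0.957, 0.876 to 1.045) and with a per-cell UMI gate (ratio 0.994, 0.917 to 1.077), both intervals including 1.

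The comparison of the aged+AA with the aged library asked how the blood of aged mice differed after AA. CD8 T-like cells held 2641 of 11089 aged+AA cells (23.8%, 23.03 to 24.6%), 2.38 times the aged share (2.21 to 2.56) and 1.03 times the young share (0.975 to 1.10). CD4 T-like cells held 15.9%, 1.45 times the aged share (1.35 to 1.57) and 0.417 times the young share. The number of CD8 T-like cells per CD4 T-like cell was 0.605 in the young, 0.917 in the aged and 1.50 (1.41 to 1.59) in the aged+AA library. Among T-like cells the CD8 T-like share was 58.3% in the aged+AA library. This was 1.28 times the aged share (1.19 to 1.38) and 1.57 times the young share (1.48 to 1.66), so on this denominator it lay farther from the young library. Such values depend on how clusters are cut and named. At resolution 0.5 the ratio of CD8 T-like shares of T cells was 0.957 (0.876 to 1.045) for aged over young and 1.08 (0.992 to 1.19) for aged+AA over aged. The CD8 T-like class then held 1822 young, 696 aged and 1593 aged+AA cells. T cells of no named class numbered 214, 377 and 1139, in place of 8, 79 and 67. Gamma-delta T-like cells held 0.864%, 0.266% and 0.559% of the 3 libraries, but similar shares of the T cells (1.39%, 1.21% and 1.37%).

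Myeloid shares were lower in the aged+AA than in the aged library. Classical monocyte-like cells numbered 31 (0.280%), 0.0327 times the aged share (0.0221 to 0.0468), and neutrophil-like cells 200 (1.80%), 0.206 times the aged share. NK-like cells held 2.21%, 0.678 times the aged share. Among T-, B- and NK-like cells alone, the CD8 T-like share was 27.1% in the aged+AA and 15.6% in the aged library, a ratio of 1.73 (1.61 to 1.86), while the CD4 T-like shares of 18.1% and 17.1% had a ratio of 1.06 (0.980 to 1.14). B-like cells were 1.16 times the aged share of all cells (1.11 to 1.21) and 0.844 times the aged share of T-, B- and NK-like cells, so their direction depended on the denominator.

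Some clusters were kept out of the named classes by rules set after the cells had been seen. Cells with both lymphocyte and erythroid genes held 1.76%, 5.92% and 4.81% of the young, aged and aged+AA libraries, an unnamed cluster led by B-lineage genes 1.77%, 3.15% and 2.73%, T cells of no named class 0.0921%, 0.809% and 0.604%, and cells with both T and B genes 0.207%, 0.338% and 0.307%.

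**Figure D1:**
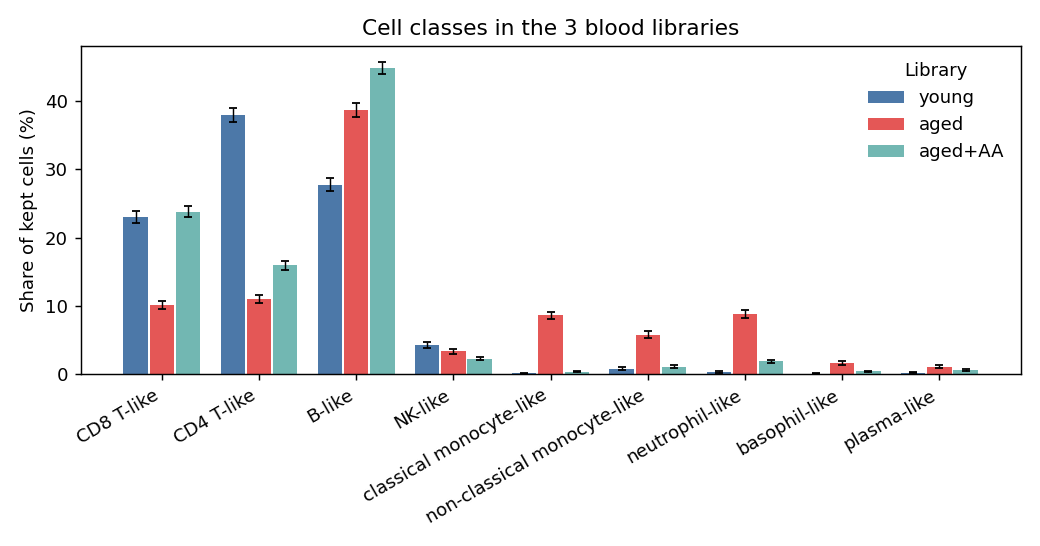
Shares of kept cells (%, vertical axis) held by 9 cell classes (horizontal axis) in the young, aged and aged+AA libraries, with exact binomial 95% intervals that cover counting error only. CD8 T-like cells stand at 23.03%, 10.0% and 23.8%, and classical monocyte-like cells at 8.55% in the aged library against 0.280% in the aged+AA library.

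Expression was then compared within classes, with each class scaled to CPM. On this scale the median gene was not at 0: in CD8 T-like cells the log2 median over 11585 genes was 0.34 for aged over young and -0.15 for aged+AA over aged, in CD4 T-like cells 0.42 and -0.18, in B-like cells 0.27 and -0.14, and in NK-like cells 0.04 and 0.03. Values of gene lists are given relative to these medians. Ribosomal protein genes took 35.3% of the UMIs of kept cells in the young, 23.4% in the aged and 32.1% in the aged+AA library, and mitochondrial genes 4.94%, 2.59% and 4.33%.

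CD8 T-like cells of the aged library held more RNA of effector, memory and migration genes and less of naive T-cell genes than those of the young library. All 23 genes of the effector and cytotoxic list had aged over young ratios above 1, and the list's relative median was 1.94 on the log2 scale (1.72 to 2.12 over Poisson redraws of the counts), above all 10000 random lists matched on expression. Ccl5, a chemokine of activated and memory T cells, was 6.68 times as high (6.57 to 6.79), Nkg7, a protein of cytotoxic granules, 2.79 times (2.70 to 2.88) and Gzmk, a granule protease, 25.3 times (17.6 to 37.5). Klrd1, an NK receptor gene also used by T cells, stood at 1.12 times (1.06 to 1.19), below the all-gene median. All 17 memory and migration genes lay above the all-gene median (relative median 1.48), with S100a6 at 14.98 times, Lgals3 at 17.1 times and Crip1 at 2.10 times. The transcription factor gene Eomes, of effector and memory T cells, was 5.51 times as high (4.66 to 6.53).

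The naive T list pointed the other way, with 14 of 15 genes below the all-gene median and a relative median of -0.43, at percentile 4.62 of the matched lists. Lef1, a transcription factor of naive T cells, stood at 0.542 times the young level (0.513 to 0.573), the interleukin-7 receptor gene Il7r at 0.657 times and the lymph-node homing receptor gene Ccr7 at 0.772 times. CD8 T-like cluster 6 was led by genes of the effector and memory lists, such as Gzmk, Lgals3 and Cx3cr1. Without it the unscaled median of the naive T list went from -0.09 to 0.054, still under the all-gene median of the whole class. The inhibitory receptor and exhaustion list lay higher (relative median 0.48, percentile 99.1), with low counts behind its largest ratios: Pdcd1, the gene of PD-1, had 5 young and 23 aged UMIs (ratio 10.4, 3.88 to 35.1) and Lag3 had 12 and 30. The interferon response list lay modestly higher (relative median 0.20, 22 of 31 genes above the all-gene median), led by Ly6a at 6.64 times.

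Immediate early genes, which switch on within minutes of a stimulus, had a relative median of -0.66 with 14 of 18 genes below the all-gene median. Fos stood at 0.617 times (0.574 to 0.662), Junb at 0.727 times and Ier5 at 0.452 times, while Nr4a1 stood at 1.97 times. All 10 measured heat shock genes lay below the all-gene median (relative median -0.50). The 13 mitochondrially encoded genes had a relative median of -1.02 and the 84 ribosomal protein genes one of -0.58, matching the lower shares of both in the aged library.

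By the fixed rule of size, the genes that stood highest in aged over young CD8 T-like cells were myeloid. Lyz2, which encodes lysozyme, had 0.815 CPM in young and 93.4 CPM in aged cells (ratio 115, 61.9 to 241), S100a9, a calprotectin subunit of neutrophils and monocytes, 2.04 and 87.3 CPM, Retnlg, a neutrophil gene, 0.326 and 20.9 CPM, and Chil3, a chitinase-like gene of monocytes, 0.0815 and 10.3 CPM (1 and 56 UMIs, ratio 127, 21.9 to 5103). RNA outside cells in the aged library held these at 3691, 4070, 777 and 346 CPM, and free RNA made up an estimated 0.835% of the UMIs of young and 1.92% of those of aged CD8 T-like cells. The lowest were Hspa2, a member of the Hsp70 family (0.0953 times, 0.0304 to 0.229), Trnp1 (0.145 times), Ddit4, a stress-induced inhibitor of mTOR signalling (0.176 times, 0.133 to 0.230) and Dapl1, a marker of naive T cells (0.335 times, 0.309 to 0.361).

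Shares of CD8 T-like cells with a UMI gave the same picture at equal depth, with each cell thinned to 1000 UMIs and 2, 0 and 7 shallower cells left out of the young, aged and aged+AA libraries. Ccl5 was seen in 17.6% of young, 62.2% of aged and 56.8% of aged+AA cells (26.8%, 71.7% and 68.8% before thinning), against 1.41%, 6.02% and 8.43% of B-like cells, which should lack it. Nkg7 was seen in 34.7%, 66.9% and 53.0% (B-like cells 0.541%, 0.932% and 1.11%), Gzmk in 0.400%, 8.38% and 2.81%, and S100a4 in 1.55%, 13.7% and 6.15% (B-like cells 0.125%, 1.70% and 0.322%). Gzmm, another granule protease gene, was seen in 1.50%, 5.01% and 7.40%. Lef1 was seen in 39.1%, 23.9% and 27.1% (B-like cells 1.58%, 0.799% and 1.09%), Dapl1 in 26.5%, 8.90% and 13.1%, and Ccr7, which B cells also express, in 39.2%, 24.5% and 37.2%. Before thinning Nkg7 was seen in 82.2%, 94.3% and 87.4%, and median depths were 5836, 5460 and 6311 UMIs in CD8 T-like and 3378, 3014.5 and 3506.5 UMIs in B-like cells. Cluster 5 held 85.7% of the young, 0.204% of the aged and 3.37% of the aged+AA CD8 T-like cells. Clusters 2, 6 and 11 held 28.3%, 31.8% and 37.8% of the aged and 40.1%, 13.2% and 41.7% of the aged+AA cells, so these values compare largely different clusters. Clusters 5 and 11 shared Fam241a, Cd8a and Cd8b1 among their leading genes, and no batch correction was made. Before the second clustering, a cluster led by Cd8b1, Fam241a, Dapl1 and Cd8a held 1679 young, 364 aged and 1171 aged+AA cells. Cluster 5 then held 1714 young, 2 aged and 89 aged+AA cells, and cluster 11 held 36, 370 and 1102. Similar CD8 T-like cells were thus parted largely by library, though overlap cell by cell was not counted. Different cluster numbers here do not show different cell types. Whether the CD4 T-like and B-like clusters below split by cell type or by library was not tested.

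**Figure D2:**
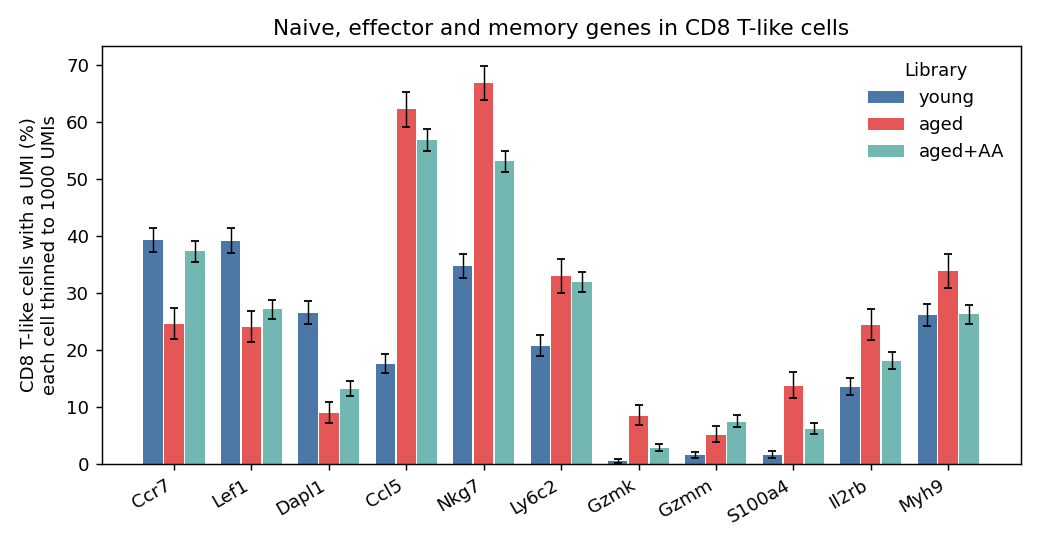
Shares of CD8 T-like cells with at least 1 UMI of a gene (%, vertical axis) after thinning each cell to 1000 UMIs, for 11 genes (horizontal axis) in the 3 libraries, with exact binomial 95% intervals that cover counting error only. Ccl5 stands at 17.6%, 62.2% and 56.8% in the young, aged and aged+AA libraries and Dapl1 at 26.5%, 8.90% and 13.1%.

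In aged+AA CD8 T-like cells the effector, memory and inhibitory receptor genes stood lower than in aged ones, and immediate early genes stood higher. The relative median of the effector and cytotoxic list was -0.33, below all 10000 matched lists, with 17 of 23 genes below the all-gene median. Ccl3 stood at 0.256 times the aged level (0.183 to 0.356) and Ccl4 at 0.374 times, both also genes of the inflammatory myeloid list. Ccl4 was lower in free RNA too (587 and 187 CPM), and after free RNA was subtracted the ratios were 0.290 and 0.387. Lower as well were the fractalkine receptor gene Cx3cr1 (0.342 times), Ccl5 (0.729 times, 0.722 to 0.736) and Nkg7 (0.683 times). Members of the same list went the other way, with Gzmm at 1.49 times (1.32 to 1.69), Xcl1 at 1.44 times and Cst7 at 1.35 times. Gzmm and Xcl1 were among the leading genes of cluster 2, with 28.3% of the aged and 40.1% of the aged+AA CD8 T-like cells. Gzmk and Cx3cr1 were among those of cluster 6, with 31.8% and 13.2%. The list values may thus follow the shares of clusters, and expression within single clusters was not compared. Without CD8 T-like cluster 6 the unscaled median of the effector and cytotoxic list was -0.08 in place of -0.48. Its interval (-0.27 to 0.006) included 0, and it lay no lower than the all-gene median of the whole class. Genes of this list lead cluster 6, so leaving that cluster out is no neutral check. It shows only that the lower list value rested largely on that cluster. The memory and migration list had a relative median of -0.45, with S100a6 at 0.542 times and Lgals3 at 0.498 times but Vim at 1.11 times. The inhibitory receptor list had a relative median of -0.37 (percentile 0.650) and the interferon response list one of -0.22 (percentile 0.0200), with Ly6a at 0.509 times and Ifi27l2a at 0.564 times.

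The naive T list had a relative median of 0.16 (percentile 63.2), and its unscaled median, with an interval of -0.07 to 0.06, changed sign when free RNA was subtracted, and was -0.18 (-0.22 to -0.05) without cluster 6 and -0.11 (-0.16 to -0.02) when cells had at most 5% mitochondrial UMIs. Klf2, a transcription factor of T-cell quiescence and migration, stood at 1.46 times the aged level (1.43 to 1.50), Ccr7 at 1.34 times and Dapl1 at 1.33 times. Immediate early genes had a relative median of 0.49, above all matched lists, with 16 of 18 genes above the all-gene median. Jun stood at 1.73 times (1.64 to 1.83), Fos at 1.59 times and Ier5 at 1.75 times, and Nr4a1 at 0.904 times. Mitochondrially encoded genes (relative median 0.49, 10 of 13 higher) and ribosomal protein genes (0.30, 74 of 84 higher) were higher too relative to all genes, as were the shares of both in the whole library.

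The genes of the fixed rule that stood lowest were Chil3 (0.0225 times, 0.00593 to 0.0609), Lyz2 (0.0542 times), Retnlg (0.0613 times) and the interferon-induced membrane protein gene Ifitm3 (0.114 times, 0.0861 to 0.149), each lower in the free RNA of the aged+AA library too, at 15.6, 235, 108 and 96.5 CPM against 346, 3691, 777 and 1471 CPM in the aged library. Those that stood highest were Gpr137c (2 and 52 UMIs, ratio 8.19, 2.16 to 69.4), Hspa2 (4.66 times, 1.91 to 14.8), Bex2 (4.41 times, 2.16 to 10.5) and Rbpms (3.94 times, 1.92 to 9.37). Hspa2 stood at 9.69, 0.923 and 4.31 CPM in the young, aged and aged+AA cells.

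Lists with small shifts followed the scaling. The list of ascorbate transporters and ascorbate-dependent dioxygenases lay at the all-gene median for aged over young (10 of 20 genes above it, percentile 50.4), so its sign turned with the scaling. For aged+AA over aged it was negative under every scaling tried, with an unscaled median of -0.26 and a relative median of -0.11 (-0.16 to 0.03, percentile 9.63). Kdm4a stood at 0.551 times, Kdm6b at 1.01 times and the ascorbate transporter gene Slc23a2 at 0.775 times (0.572 to 1.06). The unscaled medians of the myosin and actin list (0.23 and -0.08) and of the antioxidant list (0.25 and -0.15) lay between 0 and the all-gene median in both comparisons, so their signs flipped relative to all genes by the choice of scale alone.

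**Figure D3:**
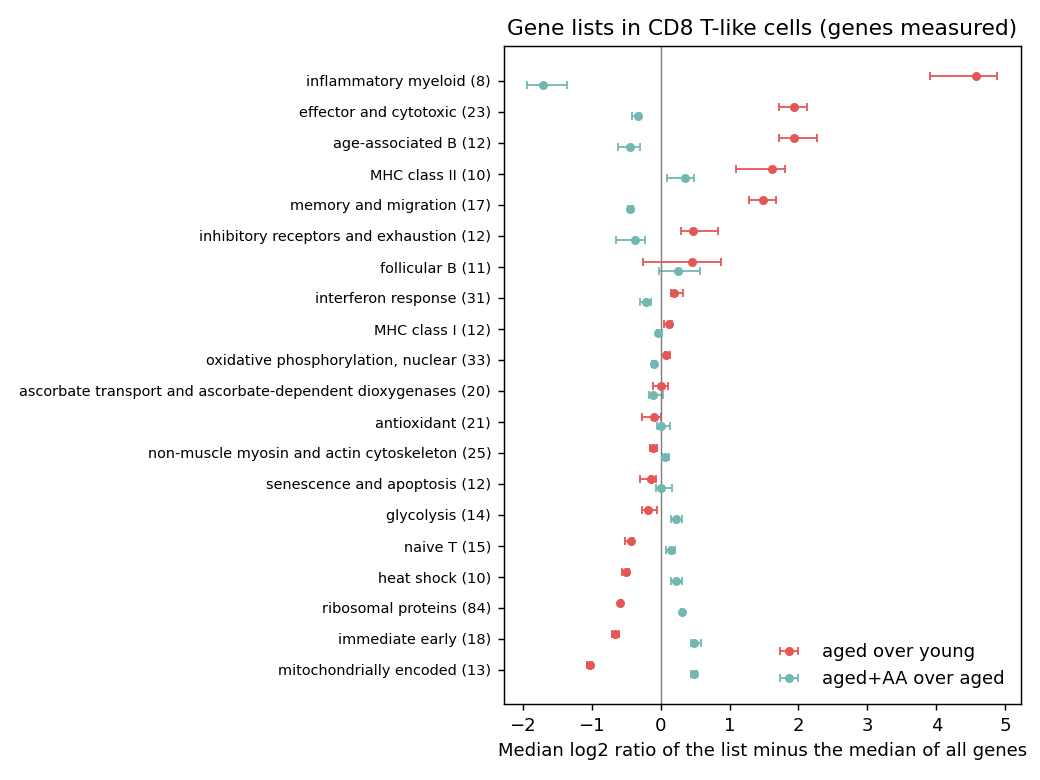
Median log2 ratios of 20 gene lists in CD8 T-like cells relative to the median of all genes (horizontal axis), with 95% intervals from Poisson redraws, for aged over young and aged+AA over aged. The effector and cytotoxic list stands at 1.94 and -0.33; signs of the glycolysis, antioxidant, ascorbate, myosin and actin, senescence, follicular B, MHC class II and naive T lists flipped in at least 1 comparison under another scaling or after free RNA was subtracted.

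In CD4 T-like cells memory genes also stood higher in aged over young and lower in aged+AA over aged. The memory and migration list had a relative median of 2.16 for aged over young, with all 17 genes above the all-gene median, and -0.72 for aged+AA over aged, with 15 of 17 below it. S100a6 stood at 16.8 times the young level (15.7 to 18.0) and then at 0.403 times the aged level, and S100a4 at 10.7 and 0.538 times. The inhibitory receptor list had relative medians of 1.34 and -0.53, with Ctla4 at 2.28 and 0.540 times and Ikzf2, the gene of Helios, at 8.07 and 0.398 times. The naive T list had relative medians of -0.58 and 0.24, with Lef1 at 0.554 and 1.24 times. By the fixed rule, Lyz2 (191 times), Ccl4 (1 and 87 UMIs, ratio 298, 52.1 to 11910.0) and Retnlg (107 times) stood highest in aged over young, all abundant in the free RNA of the aged library, and Dapl1 (0.171 times), Spon1 (0.162 times) and Ddit4 (0.229 times) lowest. Dapl1 (2.61 times, 2.25 to 3.03), Spon1 (4.15 times) and Car7 (3.94 times) stood highest in aged+AA over aged, and Lyz2 (0.0405 times), Chil3 (0.0289 times) and Lgals7 (0.0775 times) lowest. Clusters 0 and 1 held 77.9% and 10.3% of the young CD4 T-like cells, and clusters 4 and 7 held 42.4% and 49.3% of the aged and 57.0% and 31.7% of the aged+AA ones. Before the second clustering, a cluster led by Igfbp4, Ly6c1 and Pdlim4 held 3022 young, 459 aged and 1181 aged+AA cells.

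In B-like cells the immediate early genes differed in both comparisons. Their relative median was -1.02 for aged over young, with 17 of 18 genes below the all-gene median, and 0.68 for aged+AA over aged, with all 18 above it. Junb stood at 0.422 times the young level (0.412 to 0.433) and 1.90 times the aged level (1.86 to 1.95), Jun at 0.545 and 2.37 times, and Fos at 0.745 and 2.29 times. All 10 heat shock genes lay below the all-gene median in aged over young (relative median -0.71) and above it in aged+AA over aged (0.37). The interferon response list had a relative median of -0.29 for aged+AA over aged, with 27 of 31 genes lower. The list of genes of age-associated B cells, a memory-like subset that accumulates with age, had a relative median of 0.48 for aged over young (percentile 99.7), but its unscaled median of 0.75 was 0.39 after free RNA was subtracted, close to the all-gene median of 0.27. The same list was higher in CD8 T-like (relative median 1.93), CD4 T-like (2.64) and NK-like cells (0.71) too, so it was not particular to B-like cells. The unnamed cluster led by B-lineage genes, with the list member Zbtb32 among its leading genes, was not part of the B-like class. Itgam, the leading member, had 4 and 56 UMIs and is a myeloid gene too, and Apoe, the member with most counts, stood at 0.675 times. By the fixed rule, Lyz2 (72.8 times), S100a9 (38.8 times) and S100a8 (40.4 times) stood highest in aged over young, with 3691, 4070 and 3470 CPM in the free RNA of the aged library. Dapl1 (52 and 4 UMIs, 0.0558 times), the metallothionein gene Mt1 (0.134 times, or 0.0386 times after free RNA was subtracted) and Hspa1b (0.155 times) stood lowest. Dapl1 stood at 222 CPM in the free RNA of the young and 17.0 CPM in that of the aged library, and no aged counts of it were left after subtraction. For aged+AA over aged, Prss12 (4.65 times, 2.46 to 9.70), Socs3, a suppressor of cytokine signalling (2.70 times), and Jun stood highest, and Lyz2 (0.0406 times), Chil3 (0.0423 times) and Ifitm6 (0.0360 times) lowest. Cluster 1 held 81.9% of the young, cluster 2 held 62.2% of the aged and cluster 3 held 48.2% of the aged+AA B-like cells.

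In NK-like cells effector genes went both ways. Of 22 effector and cytotoxic genes, 11 lay above the all-gene median for aged over young and 10 for aged+AA over aged, and the sign of the list median flipped with the scaling in both comparisons. Immediate early genes had relative medians of -0.34 for aged over young and 0.42 for aged+AA over aged, with Jun at 0.692 (0.586 to 0.816) and 2.13 times (1.80 to 2.51). By the fixed rule, S100a9 (2 and 140 UMIs, ratio 76.7, 20.8 to 639.5) and S100a8 (3 and 114 UMIs, ratio 41.6, 13.9 to 204.9), both abundant in the free RNA of the aged library, stood highest in aged over young, and Ddit4 (0.241 times) and Spp1, the gene of osteopontin (0.249 times, 0.145 to 0.408), lowest. Klra4, which encodes an activating Ly49 receptor, stood at 1025 CPM in the young, 475 CPM in the aged and 932 CPM in the aged+AA cells, and with Jun stood highest in aged+AA over aged (1.96 times, 1.75 to 2.19), while Lyz2 (0.0476 times) and S100a9 (0.121 times) stood lowest. Classical monocyte-like cells, with 2 young and 31 aged+AA cells, fell under the minimum of 50 cells and were left out.

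Myh9, the heavy chain of non-muscle myosin IIA (ENSMUSG00000022443, GRCm38 chromosome 15, 77760587 to 77842175, minus strand), was measured in all 3 libraries. In CD8 T-like cells it stood at 309 CPM (299 to 319) in the young, 399.8 CPM (383 to 417) in the aged and 305 CPM (297 to 313) in the aged+AA library. The ratios were 1.30 (1.23 to 1.37) for aged over young and 0.763 (0.725 to 0.802) for aged+AA over aged, and with median-of-ratios scaling 1.02 (0.970 to 1.08), an interval that includes 1, and 0.849. The aged library was also highest in CD4 T-like cells (281, 425 and 308 CPM), B-like cells (197, 311 and 229.7 CPM) and NK-like cells (309.9, 468 and 355 CPM), but in non-classical monocyte-like cells (348, 441 and 485 CPM) the aged+AA library was highest. Relative to the all-gene median, the aged over young ratio of Myh9 was 1.02 in CD8 T-like, 1.13 in CD4 T-like, 1.305 in B-like and 1.47 in NK-like cells. After thinning to 1000 UMIs, Myh9 was seen in 26.1%, 33.7% and 26.2% of CD8 T-like cells (75.4%, 81.3% and 77.8% before). Thinned shares rest on total UMIs as CPM does, so they are no separate check on the scaling. Cd8a (ENSMUSG00000053977, chromosome 6, 71373427 to 71379173, plus strand) stood at 232, 323 and 261 CPM in CD8 T-like cells and Cd8b1 (ENSMUSG00000053044, chromosome 6, 71322788 to 71337494, plus strand) at 654, 659.6 and 599 CPM. Cd4 (ENSMUSG00000023274, chromosome 6, 124864692 to 124888221, minus strand) stood at 95.3, 202 and 134 CPM in CD4 T-like cells.

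**Figure D4:**
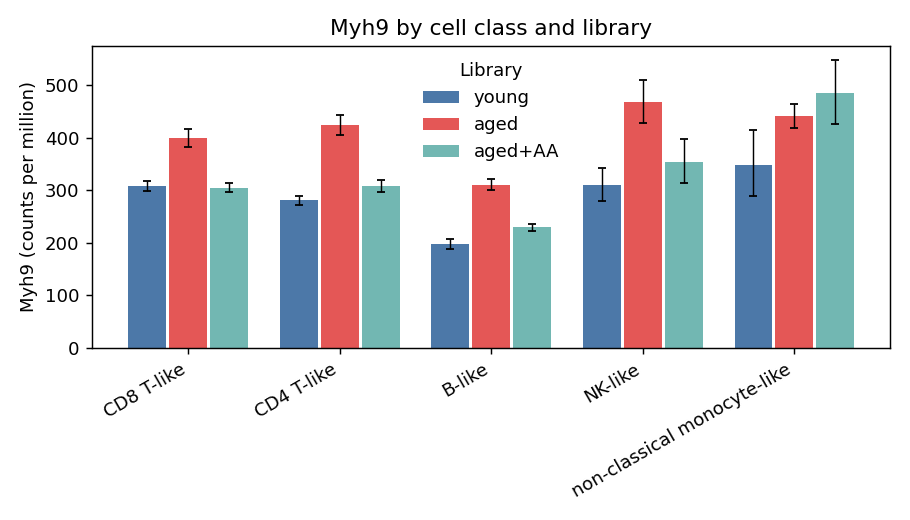
Myh9 (CPM, vertical axis) in 5 cell classes (horizontal axis) of the young, aged and aged+AA libraries, with exact Poisson 95% intervals that cover counting error only. In CD8 T-like cells it stands at 309, 399.8 and 305 CPM, and with median-of-ratios scaling the aged over young ratio is 1.02.

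Whether the aged+AA library lay on the side of the young one was asked gene by gene, with the aged cells split at random so that no cell entered both comparisons. By the fixed rule, applied to the first part of the aged cells, 4 CD8 T-like genes stood highest (Lyz2, S100a9, Ifitm2 and Gzmk) and 4 lowest (Trnp1, Ddit4, Id3 and Hspa2) in aged over young, and all of them lay toward the young level in aged+AA cells when compared with the other part. For sets this small, resampled parts without a difference ranged from none to all of the genes, so this count decides nothing. Larger sets, chosen after the data were seen, held genes at least 2-fold higher or lower in aged cells relative to the all-gene median. Of 168 such higher genes in CD8 T-like cells, 150 (89.3%) lay toward the young level by their unscaled ratio. In resampled parts without a difference the average was 49.4% (28.0 to 76.8%). These parts came from splitting the second part of the aged cells again. They held fewer cells than the comparison itself, so the ranges are no exact reference in any class. Of the 234 lower genes, whose median unscaled log2 ratio was -0.96, 158 (67.5%) did, against 49.2% (35.9 to 58.5%). With the direction also taken relative to the all-gene median, the counts were 143 (85.1%) and 185 (79.1%). On that scale the way back spanned 28.3% and 27.5% of the median aged to young difference. In CD4 T-like cells 191 of 198 higher genes (96.5%, against 22.7 to 75.3%) and 206 of 296 lower genes (69.6%, against 35.8 to 60.5%) lay toward the young level, and in B-like cells 134 of 139 (96.4%, against 41.7 to 59.0%) and 119 of 147 (81.0%, against 35.4 to 63.9%). Relative to the all-gene median these were 92.9% and 81.8% in CD4 T-like and 91.4% and 88.4% in B-like cells. In NK-like cells 17 of 20 higher genes (85.0%) did, no more than the highest value without a difference (85.0%), and 54 of 65 lower genes (83.1%, against 27.7 to 67.7%).

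Across genes of CD8 T-like cells, which are not independent replicates, the log2 ratios of both comparisons correlated with r = -0.33 when the aged cells were split and with r = -0.65 when all aged cells entered both. Unchanged simulated libraries gave 0.00 and -0.74, and covariances of 0.00 and -0.10 against the observed -0.17 and -0.29. The split correlation was -0.42 in CD4 T-like, -0.47 in B-like and -0.19 in NK-like cells. An aged library that stands apart from the other 2 libraries for any reason gives the same pattern, and 1 library per group leaves this open.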

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

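The tests on the CD8 T-like share among lymphocytes, on the monocyte gate, on Lyz2 in free RNA and on the fraction of free RNA needed were chosen only after the results they concern had been seen.

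Barcodes called as cells but left out for having under 250 genes stood out as data left out of the cell classes and their comparisons: they were 36.0% (35.951%) of called barcodes in the aged and 15.8% (15.847%) in the aged+AA library, above the 11.2% of the young library. Haemoglobin genes held 94.4%, 95.7% and 95.9% of their UMIs in the young, aged and aged+AA libraries.

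CD8 T-like cells held 2.38 times the aged share in the aged+AA library. Dilution by myeloid cells in the aged library does not account for all of it, since the ratio among T-, B- and NK-like cells alone was 1.729 (1.606 to 1.863). Cell calling, filters and clusters do not either: on every barcode with 500 UMIs and no other filter, CD8 T gate barcodes over T and B gate barcodes had a ratio of 1.823 (1.687 to 1.972). A difference in how blood was drawn or separated for 1 library, mouse-to-mouse variation and the treatment may each contribute, and none was tested.

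Monocyte-like and neutrophil-like cells held far smaller shares in the young library (0.760% and 0.207%) than in the aged library (14.3% and 8.75%), and smaller ones in the aged+AA library (1.29% and 1.80%). The gene, mitochondrial and doublet filters are argued against as the whole cause: before them the monocyte gate took 13 of 10849 young and 1035 of 17558 aged barcodes, a ratio of shares of 49.194 (28.64 to 92.706), and 0.268% of aged+AA barcodes. The neutrophil gate took 0.175%, 6.37% and 1.51% of young, aged and aged+AA barcodes, a smaller difference between the aged and aged+AA libraries. Cells broken open before or during loading would leave their RNA free, but Lyz2 was 19.525 times as high in the aged as in the young free RNA (16.454 to 23.346), and the neutrophil gene Retnlg stood at 22.7, 777 and 108 CPM in the free RNA of the young, aged and aged+AA libraries. Age alone could bear only on the young library and treatment alone only on the aged+AA library. A different separation of myeloid cells from lymphocytes before loading of the aged library could give both differences, and so could age and treatment together. None of these was tested.

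The myeloid genes Lyz2, S100a9, Retnlg and Chil3 were higher in aged CD8 T-like cells. Free RNA of the aged library is a candidate explanation: the fraction of free RNA these genes needed over the haemoglobin-based fraction was 1.358 (median over the 4 genes) in the class farthest from 1, and 1.036 in the nearest of the 4 lymphocyte classes. After subtraction at the haemoglobin-based fraction Retnlg still stood at 44.1 times and Chil3 at 169 times the young level (64.0 and 127 times before). These ratios rest on 4 and 1 young UMIs before subtraction. No young counts of Lyz2 and S100a9 were left, so these had no ratio. The haemoglobin-based fraction does not account for all of the values, and the rest stays open. Droplets with a T cell and a myeloid cell were argued against by the spread of Lyz2: cells with 4 or more Lyz2 UMIs held 2.372% of the Lyz2 UMIs of aged CD8 T-like cells, against 2.747% under a Poisson spread by depth.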

How the results depend on the processing

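The alternatives with T-, B- and NK-like cells as denominator, those without erythroid and mixed erythroid clusters and those without CD8 T-like cluster 6 were chosen only after the results had been seen. Cluster 6 was led by genes of the effector and memory lists, so leaving it out is no neutral check on the effector and naive T lists. No paired analysis was possible because each group had 1 library, and for the same reason no library could be left out. Of 146 values under alternatives, 92 stayed within the counting interval of the main value, 50 moved beyond it and 4 reversed, and the cause was not tested. Among the 92 are the list values with a minimum of 100 counts or 1 count per gene. These equal the main values exactly, so they say nothing on stability. The CD8 T-like share of all cells stayed below 1 for aged over young (0.340 to 0.639) and above 1 for aged+AA over aged (1.729 to 2.382) under all alternatives run. The effector and cytotoxic list stayed above 0 for aged over young (1.63 to 3.13). For aged+AA over aged it ranged from -0.68 to -0.08, and the interval of the latter, without cluster 6, included 0 (-0.27 to 0.006).

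A value counted as reversed only when its main interval excluded no change. The CD8 T-like share of T cells for aged over young reversed to 0.957 at resolution 0.5 and 0.994 with the per-cell UMI gate, both with intervals that included 1. At resolution 0.5 more T cells, 214 young, 377 aged and 1139 aged+AA, lay in no named class. The B-like share for aged+AA over aged reversed to 0.844 among T-, B- and NK-like cells. The naive T list in CD8 T-like cells for aged over young reversed to 0.054 without cluster 6.

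Values that moved follow, as ratios for shares and Myh9 and as log2 medians for lists, first for aged over young. The CD8 T-like share of all cells was 0.340 at resolution 0.5, 0.384 with the gate and 0.639 among T-, B- and NK-like cells. The B-like share was 2.44 with at most 5% mitochondrial UMIs, 1.56 with each library clustered on its own, 1.67 with the gate and 2.05 among T-, B- and NK-like cells. The naive T list was -0.22 with a flat minimum of 1000 UMIs, -0.049 and -0.20 with at most 5% and 20% mitochondrial UMIs, -0.21 at resolution 2.0, -0.43 with median-of-ratios scaling and -0.29 with totals without ribosomal, mitochondrial, haemoglobin and immunoglobulin genes. The effector list was 2.62 with the order-of-magnitude minimum alone, 2.52 with the flat minimum, 1.93 with at most 5% mitochondrial UMIs, 3.12 at resolution 0.5, 2.62 at resolution 2.0, 1.94 with median-of-ratios scaling and 1.63 without cluster 6. Myh9 was 1.02 with median-of-ratios scaling and 1.13 with the reduced totals.

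For aged+AA over aged, the CD8 T-like share of all cells was 2.20 with the flat minimum, 2.02 at resolution 0.5, 2.21 at resolution 2.0, 2.09 with each library clustered on its own, 2.15 with the gate and 1.73 among T-, B- and NK-like cells. Its share of T cells was 1.18 with at most 5% mitochondrial UMIs, 1.08 at resolution 0.5, 1.13 with libraries clustered on their own and 1.39 with the gate. The B-like share was 1.03 with at most 5% mitochondrial UMIs, 1.10 with libraries clustered on their own and 1.01 with the gate. The naive T list was 0.079 with the flat minimum, -0.11 and 0.079 with at most 5% and 20% mitochondrial UMIs, 0.058 at resolution 2.0, 0.16 with median-of-ratios scaling, 0.10 with the reduced totals and -0.18 without cluster 6. The effector list was -0.60 with the flat minimum, -0.44 with at most 5% mitochondrial UMIs, -0.68 at resolution 0.5, -0.33 with median-of-ratios scaling, -0.38 with the reduced totals and -0.08 without cluster 6. Myh9 was 0.849 with median-of-ratios scaling and 0.814 with the reduced totals.

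Few cells limited the rarer classes: 2 young classical monocyte-like cells and 7 young plasma-like cells gave wide intervals.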

Other observations

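The genes of the 3 observations below were chosen only after their values had been seen, and no test was made of them.

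Genes of regulatory T cells stood highest in the CD4 T-like cells of the aged library. Foxp3, their lineage transcription factor, stood at 9.70 CPM (8.20 to 11.4) in the young, 25.8 CPM (21.3 to 30.99) in the aged and 8.26 CPM (6.40 to 10.5) in the aged+AA library. Il2ra, the interleukin-2 receptor alpha gene, stood at 6.81, 13.2 and 4.81 CPM, Tnfrsf4 at 41.9, 102 and 69.7 CPM, and Izumo1r, which encodes folate receptor 4, at 77.1, 161 and 115 CPM. Cluster 9, in which Foxp3 led, held 5.51%, 7.59% and 3.52% of the CD4 T-like cells.

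Plasma-like cells, of which there were 7 young, 99 aged and 58 aged+AA, held mostly IgA among their heavy-chain RNA. Igha, the IgA heavy-chain constant gene, held 98.5%, 96.0% and 97.9% of their heavy-chain constant UMIs, carried by part of the cells: 3 of 7, 64 of 99 and 43 of 58 had at least 20 Igha UMIs. Ighg1 held 3.04% in the aged and 0.06% in the aged+AA library. In aged+AA B-like cells 1 cell held 85.1% of the Igha UMIs, so the class value there rests on that cell.

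Xist, expressed from the inactive X chromosome of females, stood at 841, 667 and 928 CPM in the young, aged and aged+AA libraries. The Y-linked genes Ddx3y and Eif2s3y had 0 UMIs in each library, and Uty and Kdm5d had 1 and 0 UMIs in the young, 0 and 5 in the aged and 0 and 1 in the aged+AA library. All genes placed on the Y chromosome together stood at 104 (4588 UMIs), 69.6 (3421 UMIs) and 151 CPM (8174 UMIs), and the genes behind this total were not examined.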
